A study of Homo sapiens with 20 samples.

How the data were processed

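The study measured messenger RNA by sequencing in CD8 T cells sorted from colon biopsies by their surface CD103 and CD69, a pair of proteins carried by T cells that stay in the gut wall. Of the 20 samples, 10 are labelled as coming from people without HIV and 10 from people with HIV who take antiretroviral therapy (ART). Per the labels' protocols, libraries were strand-specific and made after poly(A) selection, and read in pairs on an Illumina instrument. The protocol text also speaks of RNA from organoids, which differs from the sorted cells of the titles and the design text. Per the submitters' processing notes, Salmon 1.3.0 and the mouse genome build mm9 were used. No other aligner, counter or filter setting is given in the sources used here.

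The deposited table lists 55414 genes, and per the file headers it holds counts, TPM and log2 TPM. All 55414 gene identifiers are mouse Ensembl identifiers, and none is a human one, although all 20 samples are labelled human. The table has 60 columns of per-sample values, 20 in each of those units. Their names consist of the word sample with a running number and a code, and 0 of the 60 match a title or library name in the labels. Order is the only thing that would tie columns to samples, and it is no evidence of identity, so none of the 60 columns was used. The comparison of the ART group with the HIV-negative group, planned before the data were examined as edgeR's quasi-likelihood test with gene list tests, was therefore not run, and no fold change, p-value or replicate error is given. The depth per library is not given either, for the same reason.

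What was used is a single column that the file header names as an average. Per the file headers it follows the log2 TPM columns, and it is read here as the authors' average on the log2 scale. It is never negative and 54.6% of its entries are exactly 0, as on a log2 scale of TPM plus 1. How many of the table's libraries entered the average, and with what weights, is not given in the sources used here. It is not divided by group and has no replicates, so each value stands without an error.

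From the average, genes above 0 were counted per gene class as the table names the classes. A back-transformed sum was made by raising 2 to each average and taking off 1. It came to 820786 over all genes. Because an average of logs is not the log of an average, shares of that sum describe the column and are not shares of reads. Before the data were examined, 28 pathway lists and 10 cell type lists were fixed, holding 722 human symbols. A symbol was looked up by the same letters regardless of case, which is no test of orthology, and 657 were found. Where a symbol had more than 1 entry, as 2 symbols did, the higher average was used. Each list's median was placed among the medians of 10000 random lists of the same size drawn from all 21884 protein-coding genes (Python 3.11.15, numpy 2.4.6, pandas 2.3.3), with ties split evenly. Genes are not independent replicates, so these percentiles describe the table only. In a check on simulated lists of 20 genes, 100 random lists had a mean percentile of 48.6, and 5 of them reached percentile 95. Of 100 lists raised by 1 on the log2 scale, 100 did. The check placed each list among fewer random lists than above. Its outcome follows from how it was built, since adding 1 lifts every gene above the 75th percentile of protein-coding genes, 0.85. It shows that the calculation runs and says nothing of the fixed lists. The rule for named genes kept the PPAR and RXR genes. Its other parts rest on p-values, so the other genes named below were chosen after their values were seen, mostly as the highest or lowest members of a list. Genome coordinates are not given, since a mouse annotation was not used here.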

Results

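The study set out to compare gut-resident CD8 T cells from the colon of people with HIV on ART with those of uninfected people. The 20 samples fall into 10 labelled HIV-negative and 10 labelled ART. The columns of the expression table carry names that match neither set of labels, so the groups could not be compared, and the direction of any gene between them, PPARG included, is not reported. No name in the table shows that its columns are these 20 samples. What follows describes the authors' average per gene over the table, on the log2 TPM scale, with no replicates and no error. Each gene is given by its mouse symbol, as in the table, although the samples are labelled human, so a level is that of the mouse entry and not of the human gene of that name.

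Entries classed as small structural RNA, microRNA or ribosomal RNA held the 15 highest averages. Rn7s1 and Rn7s2, the mouse genes for the RNA of the signal recognition particle, led the table at 16.23 each. They were followed by 3 entries classed as microRNA and listed without a symbol, at 15.42 each. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 had 15.34 and 13.996. The spliceosomal U1 gene Rnu1a1 stood at 14.53, 7SK at 14.24 and the 18S ribosomal entry Rn18s-rs5 at 12.76. The microRNA entry Mir6236 stood at 15.33. The highest protein-coding entry, Gm10985 at 13.36, and the pseudogene Gm19220 at 13.31 ranked just above Rn18s-rs5. Of all 55414 genes, 25137 had an average above 0, 7240 above 1 and 622 above 5, while 30277 were listed at 0. In the back-transformed sum, the microRNA class took 23.9%, miscellaneous RNA 21.6%, small nuclear RNA 21.2%, ribosomal RNA 12.0% and mitochondrial ribosomal RNA 7.05%. The microRNA share came mainly from the 3 entries at 15.42, which share 1 value, and from Mir6236. Of the 2206 entries of that class, 481 lay above 0. The class name is the table's, and the libraries were made after poly(A) selection, so the share is no measure of microRNA in the cells. The protein-coding class took 7.93%, with 15652 of its 21884 genes above 0. Its share was 23.1% without the 20 highest genes and 14.6% when entries of a class with the same value were counted once, which made it the class of rank 3. In that count the small nuclear RNA share was 11.2%, the ribosomal RNA share 2.61% and the mitochondrial ribosomal RNA share 13.0%.

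**Figure D1:**
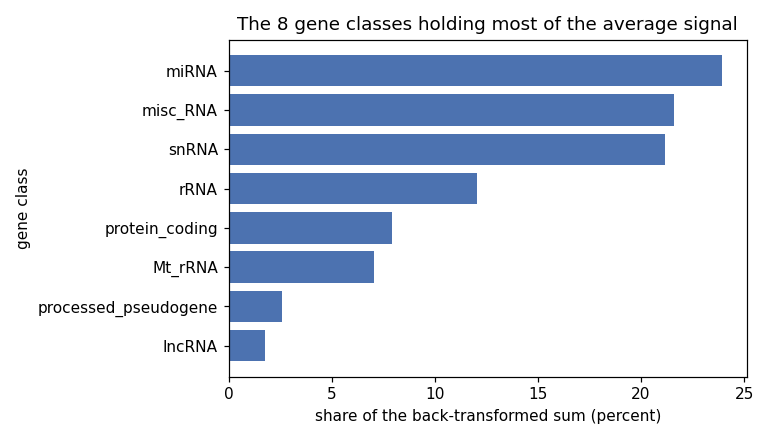
Horizontal bars give the share of the back-transformed sum of the authors' averages (percent) for the 8 gene classes with the largest shares. The class that the table names microRNA has the longest bar at 23.9%, which comes mainly from a few entries. The protein-coding class stands at 7.93%, or 14.6% with shared values counted once.

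Most genes of CD8 T cell identity were at or near 0. Cd8a and Cd8b1, the chains of the CD8 co-receptor, and Itgae, which encodes CD103, the protein used for the sort, were listed at 0. So were Trac, the constant part of the T cell receptor alpha chain, and Trbc2, a constant part of the beta chain. Trbc1, another constant part of the beta chain, had an average of 0.51. Cd69, the other residency protein of the sort, had an average of 0.990. Of the 12 CD8 T cell identity genes found, 5 were listed at 0 and 1 lay above 1, namely Cd3d, a chain of the CD3 complex, at 5.08. Its partners Cd3g and Cd3e stood at 0.56 and 0.28, and the leukocyte phosphatase Ptprc at 0.68. The list's median of 0.05 lay at percentile 14.9 among random lists of protein-coding genes, and at 54.1 when only genes above 0 were taken.

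Cytotoxic molecules and effector cytokines were also low, while the lists named for inhibitory receptors and tissue residency lay nearer the middle. Among 13 cytotoxic molecules found, 7 were listed at 0 and none lay above 1, and the highest was Srgn, the granule proteoglycan, at 0.57. Their median of 0 lay at percentile 2.30. Among 22 effector cytokines and chemokines, 13 were listed at 0, and Il21, a helper T cell cytokine, was the only member above 1, at 2.79; this list lay at percentile 0.445, or 13.2 among genes above 0 alone. The 14 genes of the inhibitory receptor list lay nearer the middle, at percentile 39.8 with a median of 0.15, and 5 lay above 1. Of these, Tigit at 8.08 and Lag3 at 1.12 are receptors. Eomes at 2.97, Tox2 at 1.73 and Tox at 1.41 are transcription factors, so the median is not one of receptors alone. Other receptors of the list were lower, with Ctla4 at 0.64, Cd160 at 0.05, Havcr2 at 0.02, and Pdcd1 and Btla at 0. The 18 tissue residency genes lay at percentile 53.0, with a median of 0.20 and Runx3, a transcription factor of CD8 T cells, highest at 2.13. Of these genes 2 lay above 1, and 5 were listed at 0, namely Itgae, Cxcr6, Cd101, Gpr15 and Klrc1.

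Genes tied to the study's question on PPARγ, a nuclear receptor that governs lipid handling, ranged in their averages from 0 to 5.25. Pparg stood at 3.07, above 95.8% of protein-coding genes, and its coactivator Ppargc1a at 3.09. Ppard, Ppara, Rxra and Rxrb had averages of 1.21, 0.22, 0.89 and 1.75. Of 24 PPARG target genes, 3 lay above 1, which were Pdk4, an inhibitor of pyruvate dehydrogenase, at 3.86, Cited2 at 2.98 and the lipase gene Lpl at 1.19. The median of these targets was 0.34, at percentile 82.1. The 25 fatty acid oxidation genes had a median of 0.32, at percentile 80.3, with Etfa highest at 2.05. The 22 genes of lipid uptake and storage had a median of 0.36, at percentile 82.7. Among genes above 0 alone, the PPARG target list lay at percentile 60.9, the fatty acid oxidation list at 33.3 and the lipid uptake and storage list at 34.1. The lipid uptake and storage list was led by Lipe, the hormone-sensitive lipase, at 5.25 and Vldlr at 2.73.

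Of the 38 lists, 11 lay at or above percentile 95 among random lists, where 1.9 would by chance. The random lists draw on all protein-coding genes, those listed at 0 included, and some fixed lists share members. The 1.9 is therefore a reference only, and the excess over it is no evidence about these cells. The highest medians were those of heat shock genes, at 3.03, and immediate early genes, at 1.93. Heat shock genes were led by Hspa1b at 8.36, Hsp90aa1 at 5.91 and Hsp90ab1 at 5.54, and 12 of 15 lay above 1. The rest of that list was near 0, with Hspe1 at 0.14, Hspa1a at 0.06 and Hspb1 at 0. Immediate early genes, which cells switch on within minutes of a stimulus, were led by Fosb at 4.27, Egr1 at 4.12 and Nr4a3 at 3.63, and 15 of 23 lay above 1. NF-kB targets had a median of 0.98, with Tnfaip3 at 6.23, Traf1 at 5.13 and Nfkbia at 4.98. Glycolysis, hypoxia response, TGF-beta signalling, and amino acid and mTOR genes had medians of 0.84, 0.80, 0.84 and 0.97. The citric acid cycle, autophagy, cytosolic ribosomal proteins, and recirculation and memory genes, with 1.15, 0.68, 1.12 and 0.69, complete this set. At or below percentile 5 lay 4 lists. They were the cytotoxic molecules, the effector cytokines, the genes of macrophages, monocytes and dendritic cells, at percentile 1.08 (59.5 among genes above 0 alone), and those of gamma-delta T, NK and innate lymphoid cells, at percentile 4.36. With members and background limited to genes above 0, 7 of the 11 kept their place, and of the 4 only the cytotoxic molecules did; the gamma-delta T, NK and innate lymphoid list had too few genes above 0 for a value.

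Genes that nucleated cells use in general differed widely in their averages. The actin gene Actb stood at 9.43 and the elongation factor Eef1a1 at 6.53. The glycolytic enzyme Gapdh had 0.80 and the class I light chain B2m 0.19, above 74.0% and 50.2% of protein-coding genes. The 50 cytosolic ribosomal protein genes ran from 2 listed at 0 up to Rps27 at 6.04, with a median of 1.12 and quartiles of 0.28 and 2.62. Among 12 mitochondrially encoded protein genes, mt-Nd6 stood at 11.58, whereas the next, mt-Co1 and mt-Nd5, had 2.03 and 1.32.

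Markers of other cells the sort could have held differed by cell type, with colon epithelium and stroma above the protein-coding median of 0.18 and the others below it. The colon epithelium list had a median of 0.36 over 22 genes, at percentile 82.8 (46.2 among genes above 0 alone). Of these genes 7 lay above 1, led by the keratin Krt8 at 4.003 and the adhesion molecule Epcam at 3.70. Others of the list lay at or near 0, among them Fabp1 at 0.09, Phgr1 at 0.07, Krt20 at 0.03 and Guca2a at 0. Stroma and endothelium had 0.49, at percentile 88.9 (80.9 among genes above 0 alone). Of their 14 genes 5 lay above 1, led by Pecam1 at 5.10, with Col1a1 next at 1.63. Other endothelial genes of the list lay at or near 0, with Vwf at 0.10, Cdh5 at 0.02 and Plvap at 0. The stromal gene Pdgfrb was also listed at 0. B and plasma cells had 0.08, at percentile 23.3, and none of their 13 genes lay above 1. The lists of mast cells, CD4 and regulatory T cells, and MAIT cells had medians of 0.17, 0.09 and 0.14, and that of gamma-delta T, NK and innate lymphoid cells had 0.

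**Figure D2:**
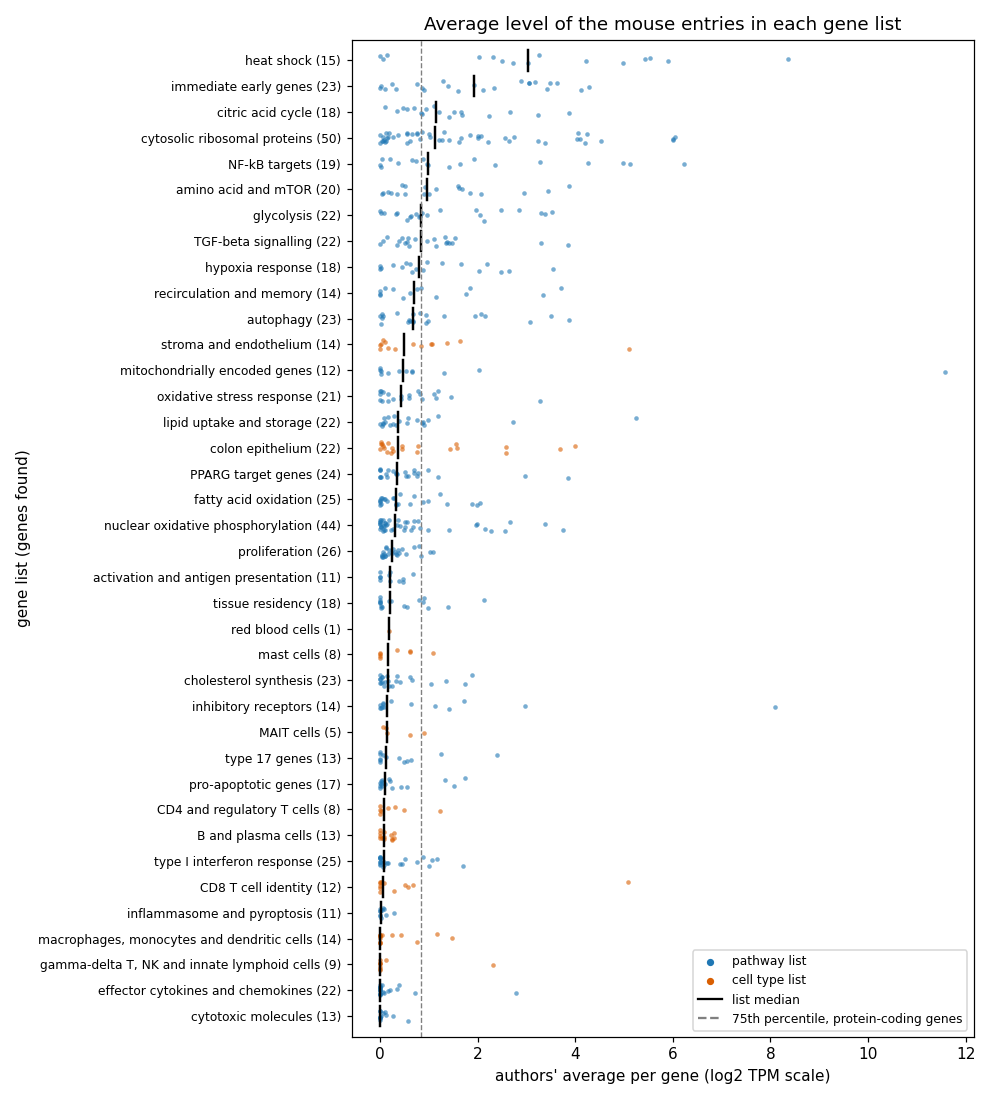
Each point is a gene of a fixed list, placed by the authors' average (log2 TPM scale, x axis), with lists in rows ordered by their median (black bar) and the dashed line at the 75th percentile of protein-coding genes, 0.85. Heat shock genes have the highest median at 3.03, and the CD8 T cell identity list lies near the bottom at 0.05 with Cd3d apart at 5.08.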

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

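All alternatives here were chosen after seeing the data, because the planned ones need per-sample columns matched to a group and were not run: other normalizations, filters, tests, covariates, surrogate variables, thresholds and leaving out libraries. No paired analysis was possible because the columns carry no replicate number of the labels. The labels also give no pairing: the groups are people without HIV and people with HIV, and replicates are numbered within each group. Equal numbers in both groups are therefore no sign of a pair. The number of genes listed above 0, 25137, became 19448 above 0.1 and 7240 above 1. The protein-coding share of the back-transformed sum, 7.93%, became 23.1% without the 20 highest genes and 14.6% when entries of a class that share a value were counted once. With members and background limited to genes above 0, 26 of 36 lists stayed on the same side of percentile 50. Of the 11 lists at or above percentile 95, 7 remained there: the citric acid cycle, immediate early genes, NF-kB targets, heat shock, TGF-beta signalling, amino acid and mTOR genes, and ribosomal proteins. Of the 4 lists at or below percentile 5, the cytotoxic molecules remained there. The lists of gamma-delta T, NK and innate lymphoid cells and of red blood cells had fewer than 3 genes above 0 and gave no value. The CD8 T cell identity list moved from 14.9 to 54.1, and the PPARG target, fatty acid oxidation and lipid uptake lists from 82.1, 80.3 and 82.7 to 60.9, 33.3 and 34.1. The macrophage, monocyte and dendritic cell list moved from 1.08 to 59.5, nuclear oxidative phosphorylation from 84.9 to 44.6 and proliferation from 67.4 to 7.0, the largest move, while the inflammasome list entered the lower range, from 8.68 to 1.23. This alternative raises the median of a list with members at 0 by construction and changes the background too; the proliferation list had no member at 0, so its move came from the background alone. The depth behind the average is unknown, since the count columns were not used here, and an entry listed at 0 may reflect low depth.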

Other observations

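Among lists not described in full above, the type I interferon response had a median of 0.08 over 25 genes, led by Ifit1 at 1.70. The proliferation genes had a median of 0.25 over 26, with Mcm7 at 1.09. The 14 genes of recirculation and memory had a median of 0.69, with Cx3cr1, a chemokine receptor of circulating effector cells, at 3.71 and Satb1 at 3.33. Cholesterol synthesis genes had a median of 0.17 and inflammasome genes one of 0.02. The medians were 0.11 for type 17 genes, 0.20 for activation and antigen presentation, 0.10 for pro-apoptotic genes and 0.43 for the oxidative stress response. They were 0.31 for nuclear oxidative phosphorylation and 0.46 for mitochondrially encoded genes. For activation and antigen presentation, 11 of 18 symbols were found and none of them was an HLA gene. Its median is thus mostly one of activation genes. Of the red blood cell list only Alas2 was found, at 0.18. The authors' column headed LowExpLowVar marks 35966 genes, all with an average under 0.1, and leaves 19448 unmarked, all above 0.1.

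Some entries shared their values exactly. Among genes above 0, 595 entries shared an average with another entry of their class, over 177 values. The largest such group above an average of 10 held 32 ribosomal RNA entries at 11.455, n-R5s104 among them, and 6 small nuclear RNA entries stood at 14.53.

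Of the 12 T cell identity genes found, 5 were listed at 0 in a table labelled as sorted T cells, although Cd3d stood at 5.08 and the list as a whole lay at percentile 14.9, or 54.1 among genes above 0. The tests of this pattern were chosen after the result was seen, and none of them decided it. A candidate explanation is that human reads were assigned to mouse transcripts. The nuclear oxidative phosphorylation list, of genes that nucleated cells share, had its median at percentile 57.5 of protein-coding genes (95% bootstrap interval 43.4 to 67.3). That interval lies below the bound of 75 set for a low place. But the citric acid cycle, glycolysis and ribosomal protein lists had medians at 80.6, 74.9 and 80.1, with intervals that include 75. These places are relative to the other protein-coding genes of the same column, which such an assignment of reads would also affect. Neither a high nor a low place could therefore decide for or against this explanation. Each interval comes from resampling the genes of its list. It gives the spread among those genes, which are not independent replicates, and no error of the data. For nuclear oxidative phosphorylation, 44 of 55 symbols were found, with Atp5pb alone of the ATP synthase genes. The highest median of the other cell type lists, 0.49 for stroma and endothelium, fell short of the 0.85 set for cells other than T cells, but these markers are read on the same mouse entries, so that explanation is not excluded. Carry-over of RNA without a poly(A) tail would lower protein-coding genes alike, so the 92.1% of the back-transformed sum outside that class says nothing of the place of T cell genes within it, and the high place asked of the shared lists was not met.

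That the table may belong to other samples than those labelled was not tested and remains open beside the 3 explanations above, whose test of human reads on mouse transcripts gave percentiles of 57.5, 80.6, 74.9 and 80.1 and decided nothing. No comparison of mouse with human sequences was made. No biological explanation was tested, since the columns could not be matched to the groups.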
